A study of Rattus norvegicus with 16 samples.

How the data were processed

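The samples were 16 mammary carcinomas of female Sprague-Dawley rats, each hybridised on 1 two-colour Agilent oligonucleotide array for comparative genomic hybridisation. Tumour DNA carried Cy5 and DNA of normal rat liver carried Cy3, per the labels. Groups came from the labels: 7 tumours of non-irradiated rats, 4 of rats given 0.485 Gy of neutrons and 5 of rats given 0.5 Gy of gamma rays at 0.5 Gy per minute, with both exposures at 7 weeks of age. The labels also carried a code per tumour. The 16 tumours had 13 codes, and 3 codes were each shared by 2 tumours of one group (K0813, K2476 and K1169). What the code stands for was not stated, so each tumour was counted as 1 replicate, and the p-values measure the spread between these tumours. The 7 non-irradiated tumours had 5 codes and the 5 gamma tumours 4. In the fit over bins of 1 Mb described below, with code as a random block, the correlation within a code was 0.952. It rests on 3 pairs. The tumours of K0813 and K1169 had only 0.016 to 0.032% of the genome in called changes, and those of K2476 had 2.89% and 0.037%. The correlation thus does not show that tumours of one code share changes. Counting tumours may still overstate the number of independent samples.

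The authors deposited 1 scanner file per array. Its log10 ratio of Cy5 over Cy3 was, per the file headers, computed by Agilent Feature Extraction with protocol CGH_105_Dec08 from background-subtracted, spatially detrended intensity values with linear dye normalization. The headers gave version 10.5.1.1 of that software, and the submitters' processing notes gave 10.7.3.1. Probe positions were on the rat build rn4 (RGSC v3.4), per the file headers. The authors also deposited a value table of log2 ratios for the same arrays. Set against the scanner values, it had the same direction, slopes of 0.814 to 1.00 and correlations of 0.901 to 1.00 per array, and column medians between -0.02 and 0.01. The step that made it was not given in the sources used here. The arrays were uneven along the genome: the SD of bins of 1 Mb outside called changes, relative to their chromosome, was 0.02 in neutron 1 and 0.09 in non-irradiated 5. The value table lowered this SD by 27.7% to 37.5% in the 5 arrays least like it (non-irradiated 5 and 6, neutron 4, gamma 1 and 2) and by 0.9% or less in neutron 1 and 2. The scanner values were the main setting, and the value table was an alternative.

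Control spots and spots with an outlier flag on an array were left out, saturated spots were kept, and spots of one probe were averaged. This left 170012 probes on chromosomes 1 to 20 and X at a median spacing of 10.72 kb. Over 99.7% of spots were well above background in both channels on each array. The log10 ratio was turned to log2 and centred on each array's median, with no loess. The spread between neighbouring probes was 0.094 to 0.144 log2 units per array. Their number and this spread set the precision of a level only as far as probe noise goes. The unevenness along the genome comes on top. In non-irradiated 5, bins of 1 Mb outside called changes lay between -0.241 and 0.266 relative to their chromosome. Probes more than 3 spreads from the running median of 5 probes were pulled in to 3 spreads. Each chromosome was segmented by exact penalised least squares with a penalty of 36 squared spreads per change point, in Python 3.11.15 with numba 0.67.0. A segment's level was the median of its probes. Segments of at least 5 probes and a level of 0.25 or more in size were called, and neighbouring called segments of one direction made 1 copy-number aberration (CNA). CNAs under 10 Mb were focal, and those over at least 80% of a chromosome's probes were chromosome-scale. Segments under 10 Mb with a level of 0.8 or more in size were high-amplitude.

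The segmentation was tested on simulated data, with CNAs planted in the residuals of the 16 arrays. Of 128 planted CNAs of 20 probes, 91.4% were recovered at a level of 0.3 and 100.0% at 0.5. Of those of 5 probes, 0.8% were recovered at 0.3, 69.5% at 0.5 and 100.0% at 0.8. Without planted CNAs, the residuals of the 16 arrays gave 1 false CNA. The residuals were the values less the segment levels found by the same segmentation. Steps and unevenness that it can find had thus been taken out beforehand. The rate of false calls on the uneven arrays themselves was not measured.

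The number of CNAs, the percent of the genome altered and the number of focal losses were compared between each pair of groups by an exact two-sided permutation test of the difference of means. The same test was run for 11 secondary measures and for irradiated against non-irradiated tumours, with Benjamini-Hochberg adjustment over all 56 tests. Mean log2 ratios of the 21 chromosomes were tested the same way, adjusted over the chromosomes of a contrast. The share of tumours altered was compared over bins of 1 Mb, with a family-wise exact p from the largest difference over all bins. Bins altered in more tumours than the 95th percentile of the maximum in 1000 random rotations of each tumour's calls were taken as recurrent. Mean log2 ratios of 2718 bins of 1 Mb with at least 10 probes were fitted with limma 3.58.1 in R 4.3.3 over all 16 tumours, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. On simulated bins with the spread of these tumours, with 200 bins shifted in the neutron tumours, the fit for neutron minus non-irradiated recovered 80% at a shift of 0.3 and 100% at 0.6. At these shifts 8 and 7 bins without a shift passed as well. The values were drawn as normal and independent between bins, with all neutron tumours shifted alike. In the tumours, bins of a chromosome moved together, so the recovery on real bins was not measured. These tests, the thresholds and the alternatives were fixed before the data were examined, except for the alternatives named as added in the closing section.

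The plan had been to test genes and 8 fixed gene lists. The scanner files pair no probe with a gene, and a gene annotation of rn4 was not used here. The fit was therefore run on bins, listed before the files were opened as an alternative to genes, and regions are named by position in place of genes. The rule for genes was applied to bins: per contrast, the 10 with the largest difference among those past the threshold, 1 per 10 Mb, or, where none passed, the 5 with the smallest p. The other parts of the rule named high-amplitude segments and regions altered in several tumours. The gene lists were not tested.

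Alternatives were call thresholds of 0.15 and 0.35, penalties of 25 and 64, minimums of 3 and 10 probes, centring on the commonest segment level (the mode), normexp background correction with an offset of 50, the value table, dim probes or chromosome X left out, tumours of one code averaged, mean ranks, small CNAs shared with a tumour of another code left out, code, slide or scan day as a block, segment levels, 2 groups only, bins of 5 Mb, focal losses under 3 Mb, and each tumour left out in turn. The normexp alternative used median spot signals, where mean signals had been planned. A correction for GC content was not run, because probe sequences and the genome were not used here. The arrays lay on 4 slides scanned on 2 days. Slide 1 held non-irradiated 2 and 4 and gamma 2 and 5, and slide 2 held non-irradiated 1 and 3 and gamma 1 and 3. Slide 3 held non-irradiated 5, 6 and 7 and neutron 4, and slide 4 held neutron 1, 2 and 3 and gamma 4. Slides 2 and 4 were scanned on day 1, and slides 1 and 3 on day 2.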

Results

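The copy-number profiles of 16 rat mammary carcinomas were measured against normal liver DNA: 7 tumours of non-irradiated rats, 4 of neutron-irradiated rats and 5 of gamma-irradiated rats. The design asked whether mammary carcinomas that arise after neutron or gamma irradiation carry other copy-number changes than those of non-irradiated rats. All values below are log2 ratios of tumour over liver on build rn4, where 0 is the median of the array, a positive level is a gain and a negative level a loss. In all, 156 CNAs were called. The tumours differed widely within each group: 8 of the 16 carried changes over less than 0.1% of the genome, and at the other end 49% of the genome of gamma 4 was altered.

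**Figure D1:**
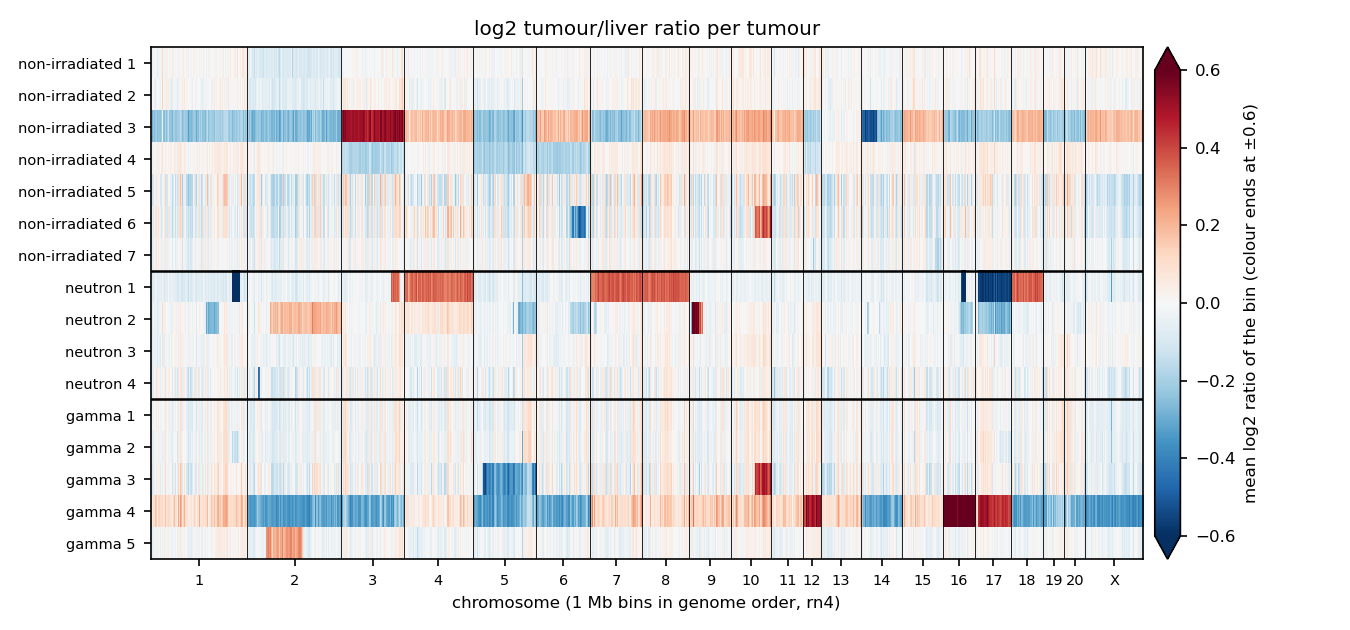
Mean log2 tumour/liver ratio of 1 Mb bins (colour, red for gains and blue for losses) along chromosomes 1 to 20 and X, with 1 row per tumour and black lines between the 3 groups. Whole chromosomes stand out in non-irradiated 3, neutron 1 and gamma 4, and non-irradiated 1, 2, 5 and 7, neutron 3 and gamma 1 and 2 show no block of a called change.

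Among the 7 non-irradiated tumours, non-irradiated 3 was imbalanced on 20 of 21 chromosomes at a median level of 0.15 or more in size, a count chosen after the data were seen. It gained the whole of chromosome 3 (level 0.52) and lost chromosome 14 from 0.0 to 40.0 Mb (-0.51). Chromosome 13 lay at 0.00, and most other chromosomes lay near 0.20 or -0.22, on either side of the array median and mostly below the call threshold. Centring decided which of them counted as changed. With mode centring 11 chromosomes lay at 0.15 or more and 0 at -0.15 or less, and chromosomes 1, 5, 7, 16 and 17 lay between -0.003 and 0.009. With median centring 6.29% of its genome was called gained and 6.32% lost, against 48.0% gained and 1.44% lost with mode centring. Non-irradiated 6 lost 3 stretches of chromosome 6, 2.41 Mb from 96.6 Mb (-0.34) and the stretches from 99.9 to 123.5 Mb (-0.38) and 123.8 to 136.4 Mb (-0.38), and gained the distal part of chromosome 10, from 82.8 to 110.7 Mb (0.38, with a peak of 0.95). Non-irradiated 7 shares its code with non-irradiated 6 and had none of these changes, with 4 CNAs over 0.037% of the genome. Non-irradiated 4 had lower levels over chromosomes 3 (-0.17), 5 (-0.17), 6 (-0.18) and 12 (-0.13), which did not reach the call threshold. Non-irradiated 1, 2 and 5 carried 3, 1 and 3 CNAs, all focal.

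The comparison of neutron with non-irradiated tumours rested mainly on neutron 1 and neutron 2. Neutron 1 gained chromosomes 4 (0.34), 7 (0.36), 8 (0.36) and 18 (0.36) nearly whole and lost chromosome 17 (-0.57). It also lost chromosome 1 from 225.1 to 247.0 Mb (-0.76) and chromosome 16 from 50.2 to 63.0 Mb (-0.69), and gained chromosome 3 from 132.9 to 157.9 Mb (0.35). Neutron 2 carried an amplification of chromosome 9 from 5.9 to 24.9 Mb, with a mean level of 0.88 over 11 segments and a peak of 1.42, a 2.68-fold ratio, between 10.27 and 10.73 Mb. It also lost chromosome 17 from 40.4 to 72.1 Mb (-0.29) and from 72.5 to 97.2 Mb (-0.27), chromosome 16 from 50.1 to 57.4 Mb (-0.26), chromosome 5 from 122.1 to 144.1 Mb (-0.26) and chromosome 1 from 153.8 to 188.8 Mb (-0.26), levels close to the call threshold. Neutron 4 lost 5.27 Mb of chromosome 2, from 27.4 to 32.7 Mb (-0.41), and neutron 3 had 2 focal losses over 0.006% of the genome.

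Neutron tumours carried 7.75 ± 6.29 CNAs (mean ± SD, n = 4) and non-irradiated tumours 6.43 ± 6.43 (n = 7). No difference was detected (exact permutation p = 0.821), which with so few tumours does not show that the groups are alike. The percent of the genome altered was 7.97 ± 12.1 against 2.23 ± 4.70 (exact permutation p = 0.255), and focal losses numbered 2.50 ± 1.00 against 2.57 ± 2.23 (exact permutation p = 1). Losses on chromosome 16 from 50 to 57 Mb and on chromosome 17 from 40 to 97 Mb were called in 2 of 4 neutron tumours and in 0 of 7 non-irradiated tumours, a difference of 50 percentage points. It was the largest over all bins and had a family-wise exact permutation p of 0.258. Non-irradiated 3 lay just short of the call at both places (-0.25 and -0.23), but at -0.02 and -0.00 with mode centring, where neutron 2 lay at -0.25 and -0.27. The mean log2 ratio of chromosome 17 was -0.20 ± 0.26 in neutron and -0.02 in non-irradiated tumours, a difference of -0.18 (exact permutation p = 0.0394, adjusted p = 0.827). None of the 21 chromosomes passed after adjustment, and with 330 splits the smallest adjusted p that a single chromosome can reach is 0.0636. With limma, 0 of 2718 bins passed and 13 had an unadjusted p under 0.05. The bins with the smallest p were lower in neutron tumours on chromosome 17, by -0.22 ± 0.10 (SE) at 41 to 42 Mb, and higher on chromosome 2 at 187 to 188 Mb (0.15 ± 0.07) and chromosome 7 at 39 to 40 Mb (0.16 ± 0.07), all with a limma adjusted p of 0.96. The 2 groups share only slide 3, with neutron 4 alone. Within it the differences were -5.33 CNAs, -0.761% of the genome, -0.667 focal losses and 0.004 for chromosome 17. Without neutron replicate 1 the difference was -1.095 CNAs per tumour, -0.158% of the genome and -0.06 for chromosome 17.

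**Figure D2:**
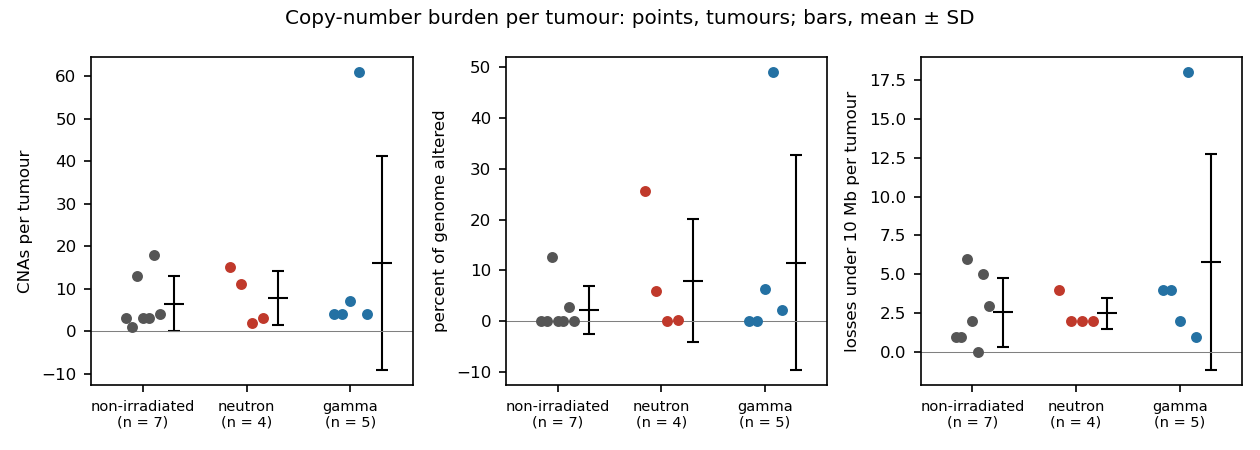
CNAs per tumour, percent of the genome altered and losses under 10 Mb per tumour for each tumour (points) of the 3 groups, with the mean ± SD of the group (bars). Gamma 4, with 61 CNAs, 49% of the genome altered and 18 focal losses, lies above every other tumour in all 3 panels. These values are with median centring, and most of its focal losses were pieces of chromosomes with a median close to the call threshold.

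**Figure D3:**
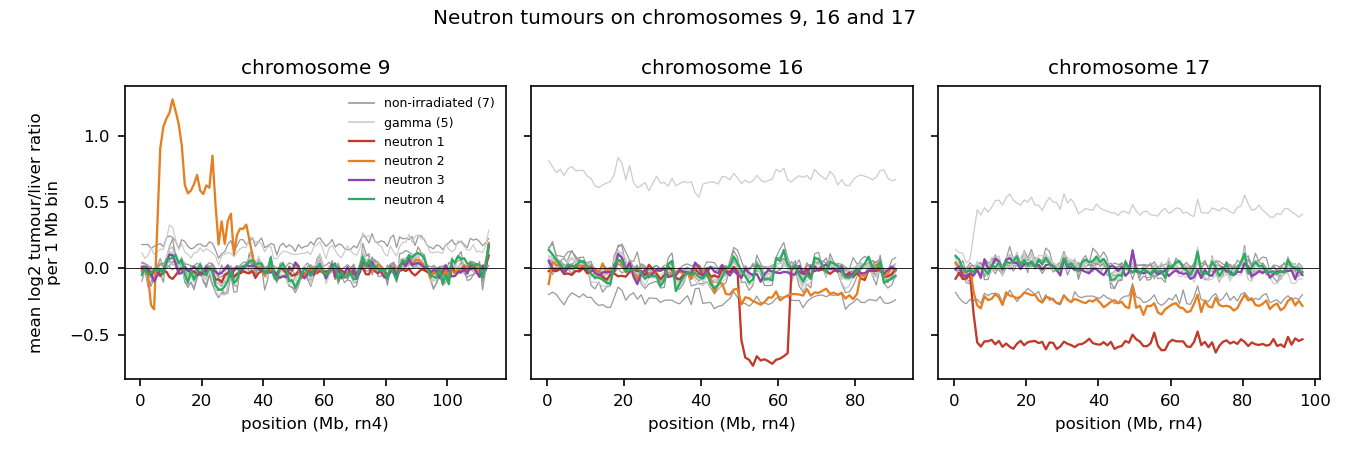
Mean log2 tumour/liver ratio of 1 Mb bins along chromosomes 9, 16 and 17 (position in Mb), with the 4 neutron tumours in colour and the 12 other tumours in grey. Neutron 2 peaks on chromosome 9, neutron 1 and 2 lie below the other tumours on chromosome 17 together with non-irradiated 3, and gamma 4 lies above on chromosomes 16 and 17.

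The comparison of gamma with non-irradiated tumours rested mainly on gamma 4. Gamma 4 was imbalanced on 14 of 21 chromosomes at 0.15 or more in size. It gained chromosomes 16 (0.70), 12 (0.51) and 17 (0.46) nearly whole, lost chromosome X (-0.36), and lost most of chromosomes 2, 3, 5, 6, 14 and 18 at levels near -0.3. Most of its 18 focal losses were pieces of chromosomes 2, 3, 5, 6, 19 and 20. The medians of these chromosomes lay between -0.32 and -0.21, close to the call threshold, so the number of pieces depended on that threshold. Here too centring decided which chromosomes counted as changed. With mode centring 12 lay at 0.15 or more and 0 at -0.15 or less, and chromosomes 2, 3, 5, 6, 14, 18 and X lay between -0.034 and 0.042. With median centring gamma 4 had 61 CNAs, with 10.9% of its genome called gained and 38.1% lost. With mode centring it had 18 CNAs, with 55.0% gained and 0% lost. Gamma 3 lost chromosome 5 from 25.4 to 126.2 Mb (-0.35) and over 4 more stretches, from 131.6 to 134.1 Mb (-0.33), 134.2 to 147.8 Mb (-0.26), 149.8 to 150.9 Mb (-0.32) and 161.4 to 173.1 Mb (-0.37), and gained chromosome 10 from 68.3 to 110.7 Mb (0.44). Gamma 5 gained 3 stretches of chromosome 2, between 50.8 and 63.7 Mb (0.28), 75.8 and 86.7 Mb (0.27) and 114.8 and 149.5 Mb (0.27). Gamma 1 and gamma 2, which share a code, had 4 CNAs each, all focal losses, over 0.032% and 0.021% of the genome.

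Gamma tumours carried 16.0 ± 25.2 CNAs (n = 5) against 6.43 ± 6.43 in non-irradiated tumours (n = 7; exact permutation p = 0.438). The percent of the genome altered was 11.5 ± 21.1 against 2.23 ± 4.70 (exact permutation p = 0.314), and focal losses numbered 5.80 ± 6.94 against 2.57 ± 2.23 (exact permutation p = 0.330). Without gamma replicate 4 the differences were -1.679 CNAs per tumour, -0.0657% of the genome and 0.179 focal losses, with 0.08 for the mean log2 ratio of chromosome 12 and -0.04 for that of chromosome 18. The largest difference over bins was a loss on chromosome 5, from 25 to 58 Mb and from 63 to 126 Mb, with 2 shorter stretches of chromosome 5, and a loss on X from 70 to 71 Mb, each in 2 of 5 gamma and 0 of 7 non-irradiated tumours (family-wise exact permutation p = 0.638). Chromosome 5 had medians of -0.22 in non-irradiated 3 and -0.17 in non-irradiated 4, short of the call, though 0.005 in non-irradiated 3 with mode centring. With the value table and a call threshold of 0.15, the stretch from 25 to 109 Mb was lost in 2 non-irradiated and 2 gamma tumours. A bin counted only where most of it was lost. Shorter losses lay inside that bin of X in non-irradiated 7, from 70.3 to 70.5 Mb (-0.72), and in gamma 2, from 70.3 to 70.6 Mb (-0.48). Each count of 2 of 5 gamma tumours includes gamma 4, which had no called loss with mode centring. The largest difference was then 0.286 of the tumours (family-wise exact permutation p = 1). Chromosome 12 averaged 0.15 ± 0.20 in gamma and -0.02 in non-irradiated tumours (difference 0.17, exact permutation p = 0.0101, adjusted p = 0.212). Chromosome 18 averaged -0.07 ± 0.13 against 0.03 (difference -0.10, exact permutation p = 0.0202, adjusted p = 0.212), and with mode centring the difference was -0.04 (exact permutation p = 0.847). None of the 21 chromosomes passed after adjustment. With limma, 0 of 2718 bins passed and 55 had an unadjusted p under 0.05. The smallest p lay on chromosome 12, at 24 to 25 Mb (0.19 ± 0.07, SE) and 36 to 37 Mb (0.19 ± 0.07), and on X at 38 to 39 Mb (-0.14 ± 0.06), all with a limma adjusted p of 0.94. The 2 groups share slides 1 and 2. Within them the differences were 2.00 and -2.50 CNAs, 1.08 and -3.07% of the genome, 1.00 and -0.50 focal losses, 0.10 and 0.15 for chromosome 12, and -0.02 and -0.10 for chromosome 18.

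Set side by side, neutron and gamma tumours differed most on chromosome 17, lost in neutron 1 and 2 and gained in gamma 4. It averaged -0.20 ± 0.26 in neutron (n = 4) and 0.09 ± 0.19 in gamma tumours (n = 5), a difference of -0.29 (exact permutation p = 0.0397, adjusted p = 0.417). Chromosome 1 averaged -0.04 ± 0.06 against 0.03 ± 0.06, a difference of -0.08 (exact permutation p = 0.0238, adjusted p = 0.417). With mode centring that difference was -0.15 (exact permutation p = 0.0635, adjusted p = 0.222). Without neutron replicate 1 the differences were -0.17 for chromosome 17 and -0.05 for chromosome 1. None of the 21 chromosomes passed, and with 126 splits the smallest adjusted p that a single chromosome can reach is 0.167. The bins with the smallest p all lay on chromosome 17, led by 41 to 42 Mb (-0.33 ± 0.11, SE) and 21 to 22 Mb (-0.35 ± 0.11), with a limma adjusted p of 0.50. With limma 0 of 2718 bins passed, and 169 had an unadjusted p under 0.05. With slide as a block in the same fit, 371 bins passed, 175 higher and 196 lower in neutron tumours, and chromosome 17 at 41 to 42 Mb had a limma adjusted p of 0.032. The 2 groups meet on slide 4 only, where gamma 4 stands alone against neutron 1, 2 and 3. In fits added after that count was seen, it was 0 without gamma 4 and 0 without neutron 2, and 1091 without neutron 4. The difference in CNAs was -8.25 (exact permutation p = 0.889), in percent of the genome altered -3.57 (exact permutation p = 0.833) and in focal losses -3.30 (exact permutation p = 0.643). Within slide 4 these were -51.7 CNAs, -38.5% of the genome, -15.3 focal losses, -0.70 for chromosome 17 and -0.19 for chromosome 1, and without gamma 4 they were 3.00 CNAs, 5.80% of the genome and -0.25 focal losses. The largest difference over bins was the same 2 losses on chromosomes 16 and 17, in 2 of 4 neutron and 0 of 5 gamma tumours (family-wise exact permutation p = 0.730).

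No difference was detected in the secondary measures either. High-amplitude focal segments numbered 2.00 ± 2.83 per neutron tumour (n = 4), 0.8 ± 1.30 per gamma tumour (n = 5) and 0.714 ± 1.11 per non-irradiated tumour (n = 7). The 6 of neutron 2 all lay in its chromosome 9 amplification. Chromosome-scale gains averaged 1.00 ± 2.00, 0.6 ± 1.34 and 0.143 ± 0.378 in the same order, all from neutron 1, gamma 4 and non-irradiated 3. Over all 56 tests of burden, the lowest exact permutation p was 0.109, for the median CNA length of irradiated against non-irradiated tumours (6.45 against 1.80 Mb), and the lowest adjusted p was 0.991. Tested over the 3 groups at once, the exact permutation p was 0.697 for CNAs, 0.555 for the percent of the genome altered and 0.428 for focal losses. Single tumours moved far between settings. Non-irradiated 5, the most uneven array, had 3 CNAs, 51 with mode centring and 98 at a call threshold of 0.15. Gamma 4 had 61, 18 and 61 in the same order. Non-irradiated 3 had 12.6, 49.5 and 95.3% of its genome altered. Neutron 1 kept 15 CNAs and 25.7% altered. Whether group differences at these settings keep their direction without such tumours was not tested.

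No bin was recurrent over the 16 tumours. A gain of distal chromosome 10, from 83 to 92 Mb and from 105 to 111 Mb, was shared by 3 tumours (non-irradiated 6, gamma 3 and gamma 4), as was a loss on chromosome 5 from 122 to 126 Mb and from 132 to 134 Mb (neutron 2, gamma 3 and gamma 4). Random rotations reached a 95th percentile of 4 tumours for gains and for losses. With mode centring the highest count was 5 tumours for gains and 2 for losses, with 95th percentiles of 5 and 3, and gamma 4 had no called loss. Other high-amplitude segments included gains of chromosome 16 at 17.82 to 19.95 Mb in gamma 4 (0.82) and of chromosome 1 at 205.18 to 205.28 Mb in gamma 4 (1.41) and at 205.07 to 205.29 Mb in non-irradiated 6 (0.88), and losses on chromosome 5 at 134.21 to 134.32 Mb in gamma 3 (-1.03) and at 134.50 to 134.57 Mb in non-irradiated 7 (-0.96).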

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

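All tests below were chosen after the result they measure was seen, except those of slide and of treatment group for the small CNAs and the comparison of each tumour with its group. Of 30 combinations of group and measure, 16 held a tumour far from the rest of its group by Dixon's criterion. For normally distributed values chance gives such a tumour in about 1 in 20 groups. These counts and percentages were skewed and partly tied, and the measures overlap, so the 16 cannot be set against that rate.

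Gamma 4 lay above the other gamma tumours in CNAs (61), percent of the genome altered (49), focal losses (18), gains (23), losses (38), focal gains (19), intermediate CNAs (20), percent gained (10.9) and percent lost (38.1). These values are with median centring. With mode centring gamma 4 had 18 CNAs and 0% of its genome lost. Non-irradiated 3 lay above its group in percent altered (12.6), gained (6.29) and lost (6.32), and non-irradiated 6 in gains (11) and focal gains (10). Neutron 1 lay above the other neutron tumours in percent gained (21) and in focal losses (4, against 2 in each of the others).

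Chromosome levels of 3 tumours (non-irradiated 3, neutron 1 and gamma 4), counted from the commonest level of each, mostly fell on a few steps. In non-irradiated 3 and gamma 4, 9 chromosomes each lay near 0.42 and 0.46, in neutron 1, 4 gained chromosomes lay near 0.39, and 61 of 63 chromosomes lay within 0.1 of a step that whole copies in a fraction of the cells of 0.679, 0.759 and 0.622 would give, though the commonest level and the first step do so by construction. These steps took the commonest level as diploid. Only on that assumption do the tables argue against such copies in one fraction of the cells as the whole account. Chromosome 13 of non-irradiated 3 lay at 0.23, a distance of 0.193 from the nearest step, and chromosome 19 of gamma 4 at 0.12. Of 30 parts of chromosomes, 4 lay over 0.1 away, the farthest being chromosome 14 from 0.0 to 40.0 Mb of non-irradiated 3, by 0.282. Another copy number at the commonest level, which would move the steps, stays open and was not tested. Changes in other fractions of the cells and compression of ratios by the array stay open and were not tested, and no biological explanation was tested.

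Losses on chromosome 16 from 50 to 57 Mb and on chromosome 17 from 40 to 97 Mb were called in 2 of 4 neutron tumours and in no other tumour, though non-irradiated 3 lay just short of the call there (-0.25 and -0.23) with median centring, and at -0.02 and -0.00 with mode centring. Whether the slide was their source cannot be told apart. Neutron 3, on the same slide, lay at -0.046 and -0.028 over these regions, above the levels of neutron 1 and 2. Gamma 4, also on that slide, had gained both chromosomes (0.67 and 0.43 over these regions), so it could not show a lowering. That leaves a single tumour as a control. A smooth wave along the genome was looked for in bins outside called changes. In neutron 1 the lowest such bin lay at -0.084 and the smaller loss at -0.57. Stretches at -0.25 or lower were called and so left out, so these bins could hardly reach -0.57 and cannot exclude a wave. They show only that the wave outside calls stayed well short of the call threshold in neutron 1. In neutron 2, where the 2 values were -0.239 and -0.25, a wave cannot be told apart. Chance stays open: in 691 of 1820 splits of the 16 tumours into 4 and 12, as many of the 4 and none of the 12 shared a change of a bin. An effect of the neutron exposure stays open as well, and was not tested apart from chance.

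Small CNAs recurred at the same places: of 56 CNAs under 1 Mb, 22 overlapped one in a tumour of another code, against at most 2 in 1000 random placements, which argues against chance placement. The 8 places included chromosome 5 at 133.98 to 134.59 Mb (8 tumours), X at 70.27 to 70.82 Mb (4) and chromosome 15 at 5.72 to 6.28 Mb (3). The tables argue against a difference common to all arrays, from probes or liver DNA, at 5 places. There 8 or more of the 16 tumours lay within 0.1 of their flanks. Such a difference stays open at the 3 other places. At 2 of them tumours lay over 0.1 both above and below their flanks, but a single tumour made up 1 side. This was non-irradiated 3 (0.16) on chromosome 5 and gamma 1 (-0.54) on chromosome 1 at 215.55 to 215.60 Mb. On chromosome 15 all 16 tumours lay over 0.1 above their flanks. An inherited difference shared within a code and an artefact of the slide cannot be told apart with 8 places: the mean correlation was 0.368 in the 3 same-code pairs (random pairs 0.551) and 0.566 within slides (random assignments 0.54), and gamma 1 and 2, of one code, lay at -0.32 and -0.29 on X but at -0.54 and 0.23 on chromosome 1 at 215.55 to 215.60 Mb. Shared small CNAs per tumour gave an exact permutation p of 0.9 over the 3 groups; the bound set beforehand, a p of 0.05 or more, was wrong as an exclusion, since with 4 to 7 tumours per group such a p does not show that groups are alike, so treatment group cannot be told apart either.

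In the fits over 1 Mb bins, where 0 bins passed, bins with an unadjusted p under 0.05 were counted in 100 splits of the tumours of each contrast. For neutron minus non-irradiated 72 splits gave at least the real 13 bins (highest other 593), for gamma minus non-irradiated 60 gave at least the real 55 (highest other 421), and for neutron minus gamma 20 gave at least the real 169 (highest other 347), so chance could not be excluded. The highest counts were several times the real ones; whether single tumours with whole-chromosome changes or another structure of the samples gave them was not tested.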

How the results depend on the processing

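The value table with a threshold of 0.15 or with mode centring, the fits without the 5 arrays least like the value table, slide as a random block, and slide or scan day as a block for burden were chosen after the data were seen, as were the fits with slide as a block that left out a tumour or moved a label. Of 270 alternatives for the 3 burden measures, 223 kept their direction, 47 changed it and 0 had an exact permutation p under 0.05 (lowest 0.0619). None of the 21 chromosomes passed under any alternative, but with all tumours a single chromosome cannot pass for neutron minus non-irradiated (smallest adjusted p 0.0636) or neutron minus gamma (0.167), whatever the setting. The cause of the changes below was not tested. A correction for GC content was not run. The spread of the probes limits short segments of low level. No paired analysis was possible because the replicate numbers follow the order of the samples and pair nothing between groups, and the 3 shared codes lie within groups.

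CNAs per tumour, neutron minus non-irradiated, turned to -17.29 at a call threshold of 0.15, -0.857 at a penalty of 25, -6.82 with mode centring, -6.64 with normexp, -6.86 with the value table and a call threshold of 0.15, -0.643 with the value table and mode centring, -5.33 with slide as block and -0.361 with scan day as block; with each tumour left out it ranged from -1.095 (without neutron replicate 1) to 3.25. For gamma minus non-irradiated it was -10.09 at a call threshold of 0.15, -6.97 with mode centring, -3.26 with the value table and a call threshold of 0.15, and -0.25 with slide as block, and ranged from -1.679 (without gamma replicate 4) to 12.57. For neutron minus gamma it was 0.15 with mode centring, and ranged from -11.25 to 3 (without gamma replicate 4).

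Percent of the genome altered, neutron minus non-irradiated, turned to -7.57 at a call threshold of 0.15, -0.36 with mode centring, -4.41 with normexp, -5.70 with the value table and a call threshold of 0.15 and -0.761 with slide as block, and ranged from -0.158 (without neutron replicate 1) to 8.39. For gamma minus non-irradiated it was -4.06 at a call threshold of 0.15, -0.973 with normexp, -1.31 with the value table and a call threshold of 0.15 and -0.998 with slide as block, and ranged from -0.0657 (without gamma replicate 4) to 12.19. For neutron minus gamma it was 1.59 at a call threshold of 0.35, and ranged from -9.46 to 5.80 (without gamma replicate 4).

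Focal losses per tumour, neutron minus non-irradiated, turned to 0.143 at a penalty of 64, 0.0357 with a minimum of 3 probes, 0.0714 with mode centring, 0.0714 with chromosome X left out, 0.589 in mean ranks and 0.0667 without the 5 arrays least like the value table, and ranged from -0.571 to 0.5. For gamma minus non-irradiated it was -4.54 at a call threshold of 0.15, -0.0286 with mode centring, -3.31 with the value table and a call threshold of 0.15 and -0.114 with the value table and mode centring. For neutron minus gamma it was 0.4 at a call threshold of 0.15, 0.1 with mode centring and 1.35 with the value table and a call threshold of 0.15.

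With slide as block, the mean log2 ratio of chromosome 17, neutron minus non-irradiated, was 0.0037. With slide as block, 371 bins of 1 Mb passed for neutron minus gamma; on chromosome 17 the differences at 41, 21, 77, 6 and 59 Mb were -0.46, -0.51, -0.47, -0.46 and -0.45. The count was 0 without gamma 4, 0 without neutron 2, and 0 with the gamma label moved to neutron 1, 2 or 3 of slide 4. It was 159 without gamma 1, 234 without gamma 3, 232 without non-irradiated 5, 634 without non-irradiated 3 and 1091 without neutron 4. With slide as a random block 0 passed. The bins named for chromosome 12 moved to between 0.08 and 0.11 without gamma replicate 4, and those for chromosome 17 to between -0.11 and -0.10 for neutron minus non-irradiated and between -0.22 and -0.20 for neutron minus gamma without neutron replicate 1. The bin on chromosome 2 at 187 Mb moved to 0.08 without neutron replicate 2, that on chromosome 7 at 39 Mb to 0.07 without neutron replicate 1 and 0.02 with slide as block, and that on X at 38 Mb to -0.08 without gamma replicate 4 and with mode centring. Of bins recurrently gained over all 16 tumours there was 1 at a penalty of 25, and of those recurrently lost 1 with normexp and 1 with the value table and a call threshold of 0.15.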

Other observations

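Chromosome 2 had a median log2 ratio of -0.09 in non-irradiated 1 and -0.07 in non-irradiated 2, which share a code and lay on different slides. In non-irradiated 4, 5 and 7, neutron 3 and 4, and gamma 1 and 2, which also had few calls, it lay between -0.04 and 0.02. In the value table the medians of the 2 tumours were -0.08 and -0.06, and those of the others lay between -0.02 and 0.02.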
